A study of Oryza sativa with 12 samples.

How the data were processed

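Rice shoots from 2-week-old seedlings were probed with dimethyl sulfate (DMS), which methylates unpaired A and C bases, at 22 °C or at 42 °C. Per the labels, 12 libraries were made, 3 with and 3 without DMS at each temperature, after poly(A) selection and random-hexamer reverse transcription. Per the labels, heat and DMS were applied in the same 10 min. The deposited files hold 1 pooled profile or value per temperature and no values per library, so the replicates could not be compared and the spread between them is unknown.

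The deposited reactivity values are a score per nucleotide, never negative, with 49.0% of positions valued at each temperature. How the authors aligned reads, counted stops, subtracted the libraries without DMS and folded the transcripts is not given in the sources used here, and neither is the genome build. Whether stop counts were log-transformed before scaling could not be settled from the values. At 22 °C the mean of the highest 2 to 10% of values was 1.04 in the median transcript and nearly the same in others, whereas at 42 °C it ran from 0.918 to 1.46 (5th to 95th percentile). The 42 °C values were therefore not scaled to their own highest values. Per the file headers, the deposited table gives coverage as reverse transcription stops per nucleotide. Coverage times the number of valued positions was a whole number, within 0.01, in 100% of transcripts, so coverage was read as stops per valued position, with no scaling to library size. Which libraries the stops came from is not given in the sources used here. The authors' other columns are the differences between 42 °C and 22 °C in single-strandedness and in folding free energy per nucleotide. The header gives the first in percent, but value times length was whole, within 0.01, in 100% of transcripts, so it was read as a fraction and is printed in percentage points. The header gives the second in kJ/mol, but value times length lay on a grid of 0.1, within 0.01 of a step, in 99.9% of transcripts, and in 2.18% after conversion from kJ to kcal, so its unit is open.

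The table held 14290 transcripts of 10619 genes, all with coverage of at least 1. Of these, 14266 had reactivities at both temperatures and 24 did not. Over these transcripts the stops came to 1.12e+08 at 22 °C and 9.56e+07 at 42 °C, with median coverage of 3.55 and 2.94. The 100 transcripts with most stops held 30.7% and 30.3% of them.

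Coverage changes were expressed as 42 °C over 22 °C, relative to the median transcript. A transcript was counted as higher or lower at a change of at least 2-fold. Each fold has an exact 95% interval (Clopper-Pearson on the stops), which covers counting error only, since neither PCR duplicates nor the spread between libraries are known. Mean reactivity was taken over positions valued at both temperatures, in transcripts with at least 100 of them. The first, middle and last 20% of the length of each transcript needed at least 20 such positions. Shares of transcripts have Wilson 95% intervals. The relation of reactivity change to coverage change was measured by the coverage of the 5% of transcripts with the largest increase and decrease.

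The 21 gene lists were patterns matched to the product names of the deposited table and were fixed before the data were examined, as were the reactivity measures, their filters and most alternatives. The measures of coverage change and their alternatives were chosen once its unit was known. The lists covered small heat shock proteins, HSP70 and HSP90 families, HSP100 and organellar chaperonins, J-domain co-chaperones, heat stress transcription factors and other heat-response co-factors. They also covered light harvesting, Rubisco small subunit and Calvin cycle, ribosomal proteins, translation factors, proteasome and ubiquitin, antioxidant enzymes, jasmonate and wound response, calcium and early stress transcription factors, mRNA decay, and auxin and gibberellin response. Marker lists covered cell division and histones, epidermis, vascular tissue, aquaporins, and organelle-encoded RNA and rRNA. The median of each list was placed as a percentile among 10000 random lists of the same size, drawn from 20 strata of mean coverage, with no p computed. A median outside the central 95% was counted as set apart, as a description of these libraries.

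The rule for named genes asked for adjusted p-values and agreement of replicates, which the files cannot give, and was adapted after the unit of coverage was known. It took the 12 largest folds in each direction with coverage of at least 5 at the temperature with the higher coverage, the 6 largest reactivity changes in each direction with coverage of at least 10 at both temperatures, and the 3 members of each list with the highest mean coverage. It took 1 transcript per gene and only transcripts with a named product. The planned replicated tests of coverage and the planned test of lists could not be run. The split by nucleotide and by untranslated region was not done, as no sequence or annotation of these transcript models was used here, and parts of 20% of the length took its place.

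Alternatives covered coverage minimums, position minimums, caps on high values, the median or the share of positions above 0.5 in place of the mean, scaling both tables to the same overall mean, leaving out 50 positions at each end, set size, matching, total stops as the scale, 1 transcript per gene, and lists without members whose product does not do what the name of the list says. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used. The procedure was tested on simulated data with 3000 transcripts, of which 200 were changed. The exact intervals held the true fold in 95.5% of transcripts, and 100% of 4-fold changes and 0% of unchanged transcripts passed the 2-fold limit. The simulated stops had counting error only, with no spread between libraries and no PCR duplicates. These shares therefore check the calculation and are not error rates for the deposited values. Reactivities set to 0.5 and 2 times their value came back at 0.499 and 1.99. They were made from the 22 °C values with noise and not from simulated stops. The simulation therefore cannot show whether a change in depth distorts mean reactivity. Of 100 lists with no shift, 2 fell outside the central 95%.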

Results

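Structure-seq2 libraries, in which reverse transcription stops at bases methylated by DMS, were made from shoots of 2-week-old rice at 22 °C and at 42 °C. The 4 groups, with and without DMS at each temperature, had 3 libraries each. The deposited values are 1 pooled coverage and 1 pooled reactivity profile per temperature for 14290 transcripts, so no value has a replicate error. Stops came to 1.12e+08 at 22 °C and 9.56e+07 at 42 °C. The comparison of 42 °C with 22 °C asked how a short heat treatment alters RNA structure in the living shoot, and which transcripts changed in coverage with it.

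Transcripts of heat shock proteins, chaperones that bind unfolded proteins, had the largest increases in coverage at 42 °C among transcripts with a named product and coverage of at least 5 at the temperature with the higher coverage. Mitochondrial small heat shock protein 22 (OS02T0758000-01) went from 1.19 to 155 stops per position, 156-fold higher relative to the median transcript (95% exact interval 145 to 169). Oshsp17.7 (OS03T0267200-01) was 145-fold higher (132 to 160), and the class I protein 17.9 (OS03T0266300-03) was 91.1-fold higher (84.1 to 98.9). A class II small heat shock protein (OS01T0184100-01) was 41.6-fold higher (39.9 to 43.4). An HSP70 (OS03T0276500-01) was 14.9-fold higher (14.7 to 15.1), and an HSP82 (OS08T0500700-01), of the HSP90 family, was 9.72-fold higher (9.53 to 9.92).

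Other transcripts among the 12 largest increases were a 70 kDa heat shock cognate protein (OS05T0460000-01, 18.9-fold), a calcyclin-binding protein (OS01T0757500-02, 18.6-fold) and an Hsp70 family protein (OS01T0840100-01, 18.2-fold). They also included a second HSP70 (OS03T0277300-01, 13.3-fold), a ubiquitin carrier protein (OS06T0506600-01, 9.33-fold) and a relative of the activator of the HSP90 ATPase (OS08T0464000-02, 8.89-fold). In all, 361 transcripts were at least 2-fold higher and 222 at least 2-fold lower. At least 4-fold changes numbered 48 and 8, and 8-fold changes 18 and 0. No test across replicates was possible, and how stops were assigned to paralogs is not given in the sources used here, where 94 transcripts had the same values as a transcript of another gene.

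Among the lists of chaperones, 11 of 24 members of the list for HSP70 and HSP90 families were at least 2-fold higher and 0 lower, with a median log2 change of 0.44, at percentile 99.98 of random lists. Without 3 co-factors in it, the activators of the HSP90 ATPase and heat shock cognate protein B, 10 of 21 were, with a median of 0.32 at percentile 98.9. The list for HSP100 and organellar chaperonins held chaperonins, Rubisco-binding subunits and RbcX proteins, which help to fold and assemble other proteins, and no HSP100. Its median log2 change was 0.88, above every one of the 10000 random lists. The 4 of its 17 members at least 2-fold higher were mitochondrial chaperonin-60 (OS10T0462900-02, 3.46-fold), a 10 kDa chaperonin (OS07T0641700-02, 2.72-fold), a chaperonin (OS06T0197550-00, 2.31-fold) and a Rubisco-binding subunit beta (OS06T0114000-03, 2.12-fold), all but the last singled out after their values were seen. The small heat shock list had 14 members, a median log2 change of 0.07 and percentile 71.9. Its 2 members at least 2-fold higher were the class II protein and the 70 kDa cognate protein, an HSP70. Its pattern missed the 3 transcripts with the largest increases, so its count does not describe that family.

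The heat stress transcription factors, regulators of heat shock genes, had 1 of 8 members at least 2-fold higher, HsfA2d (OS03T0161900-01). It went from 3.17 to 17.0 stops per position, 6.42-fold higher (6.19 to 6.67), while the list median was -0.18 at percentile 9.26. Of 64 members of the list for J-domain co-chaperones, which deliver substrates to HSP70, 1 was an rRNA methyltransferase (OS05T0567400-01) and 3 had identical values (OS05T0333500-01, OS05T0334000-01 and OS05T0334400-01). A DnaJ homolog (OS03T0787300-01) was 5.42-fold higher. A dnaJ protein (OS06T0716100-01) went from 175 to 47.7 stops per position, 3.06-fold lower (3.02 to 3.11), and a DnaJ domain protein (OS03T0323600-01), singled out after its value was seen, was at 0.352 times its coverage at 22 °C. The median of this list was -0.02 at percentile 33.2. The other heat-response co-factors had 0 of 18 members past 2-fold and a median of 0.07 at percentile 68.3.

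The medians of the list of early stress regulators and of the list of cell division and histones lay below those of random lists. Of 33 calcium and early stress transcription factors, 4 were at least 2-fold lower and 0 higher, and the median log2 change of -0.22 lay at percentile 0.26. The 4 were ERF5 (OS09T0287000-01, 4.61-fold lower, interval 4.30 to 4.94), WRKY74 (OS09T0334500-01, 4.17-fold lower, 3.96 to 4.39) and, at 0.380 and 0.441 times their coverage at 22 °C, DREB1B (OS09T0522000-01) and DREB2B (OS02T0752800-02), activators of genes of cold and drought responses. The last 2 were singled out after their values were seen. The cell division and histone markers, found in dividing cells, had a median log2 change of -0.32 over 85 members, 19 of them above 0, below every random list. Of its members with the highest coverage, histone H3 (OS06T0130900-00) was 1.66-fold lower (1.62 to 1.69), histone H4 (OS10T0539500-01) 1.11-fold lower (1.09 to 1.14) and histone H3.3 (OS03T0390600-02) 1.24-fold higher (1.21 to 1.26). Its 4 members at least 2-fold lower were all histones. Histone H2B (OS08T0490800-00), 2 histone H3 transcripts (OS05T0438700-01 and OS04T0419600-01) and histone H1 (OS03T0799000-01) were at 0.381, 0.457, 0.488 and 0.488 times their 22 °C coverage, again singled out afterwards. The 1 member at least 2-fold higher was the calcyclin-binding protein, which is not a cyclin and entered the list by the letters of its name. The list also held 24 F-box proteins with a cyclin-like domain, at a median of -0.10 (percentile 12.9), while its 44 histones had a median of -0.54, below every random list. All splits of lists by product were made after the members were seen.

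By the same rule, the largest decrease was in a transcript for a transmembrane protein (OS03T0358200-00), 7.93-fold lower. Others among the 12 largest were a heavy metal domain protein (OS02T0584700-01, 4.20-fold), a KLUNKER/PIROGI relative (OS03T0143800-00, 3.91-fold), an NB-ARC protein (OS06T0267900-01, 3.59-fold), of the domain found in immune receptors, and kinases of microbe-induced defence signalling (OS12T0113500-02, 3.35-fold, and OS11T0113700-02, 3.29-fold). The remaining 3 were an NnrU-like membrane enzyme (OS12T0405200-01, 3.12-fold), cellulose synthase-like E6 (OS09T0478300-01, 3.07-fold) and a leucine-rich repeat protein (OS07T0176500-01, 2.97-fold).

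The epidermis and the organelle and rRNA marker lists lay above random lists in coverage, and the vascular and aquaporin lists inside their central 95%. The epidermis list had a median log2 change of 0.68 at percentile 99.3 over 5 members, among them lipid-transfer protein 2 (OS11T0115350-01, 2.01-fold higher) and 2B (OS12T0115000-00, 1.92-fold). The organelle and rRNA list had a median log2 change of 0.58, above every random list. Its 4 of 14 members past 2-fold were transcripts similar to the large subunit of Rubisco, the carbon-fixing enzyme, at 2.59-fold to 2.89-fold, 3 named by rule and OS01T0899425-00 afterwards. Most of its other members encode enzymes of rRNA processing, and the 5 transcripts similar to the Rubisco large subunit alone had a median of 1.37. Among these 5, OS10T0356000-00 went from 60.3 to 131 stops per position and OS12T0207600-00 from 59.6 to 129. Whether their stops are independent was not tested. The vascular list had a median of 0.07 and percentile 73.6, with cinnamoyl-CoA reductase (OS08T0441500-01, 2.83-fold) and cinnamyl alcohol dehydrogenase (OS02T0187800-02, 2.49-fold), enzymes of lignin synthesis named after their values were seen, past 2-fold. Aquaporins, water channels, had a median of 0.13 at percentile 69.7.

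**Figure D1:**
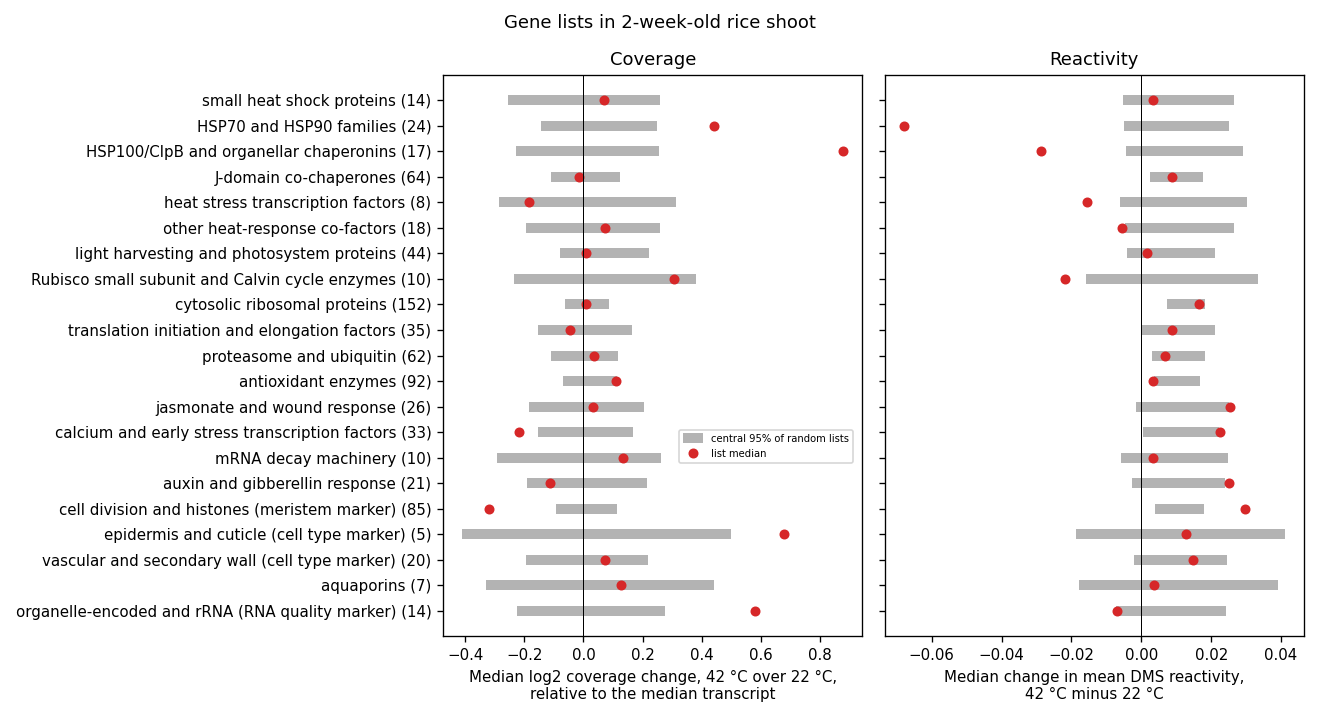
Median log2 coverage change (left) and median change in mean DMS reactivity (right), 42 °C against 22 °C, of the 21 gene lists with the number of members in parentheses; red points are list medians and grey bars the central 95% of random lists of matched coverage. In coverage, the chaperonin list, which holds no HSP100, lay at 0.88 and cell division and histones at -0.32, and in reactivity the HSP70 and HSP90 families lay at -0.0681.

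Mean DMS reactivity was higher at 42 °C than at 22 °C in 9451 of 14253 transcripts, 66.3% (Wilson 95% interval 65.5 to 67.1), with a median of 0.232 at 22 °C and 0.243 at 42 °C. The share of positions with any reactivity had a median of 35.3% at 22 °C and 31.9% at 42 °C, and the mean of the nonzero values 0.662 and 0.761. Both differed with the change in depth. Where coverage at 42 °C was at or above that at 22 °C (n = 3682), the share of positions went from 34.5% to 36.3%. The nonzero mean there was 0.660 and 0.656. In the other 10571 transcripts the share of positions went from 35.4% to 30.5%, and the nonzero mean was higher at 42 °C. The differences over all transcripts therefore cannot be told apart from lower depth at 42 °C. With coverage of at least 50 at both temperatures, the share of transcripts with a higher mean at 42 °C was 46.4% (41.1 to 51.8, n = 332). Transcripts of light harvesting and of the Rubisco small subunit were among these. Without that limit on coverage, the share was 49.0% with both tables scaled to the same overall mean. That scaling moves all transcripts by 1 factor and by itself draws the share toward an even split. The share of transcripts was 44.8% with values capped at 1, 49.2% for the share of positions above 0.5, and 19.4% for the median in place of the mean (n = 2212). Most transcripts have more zero than nonzero values, which puts their median at 0, so the last share describes only a part of them.

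**Figure D2:**
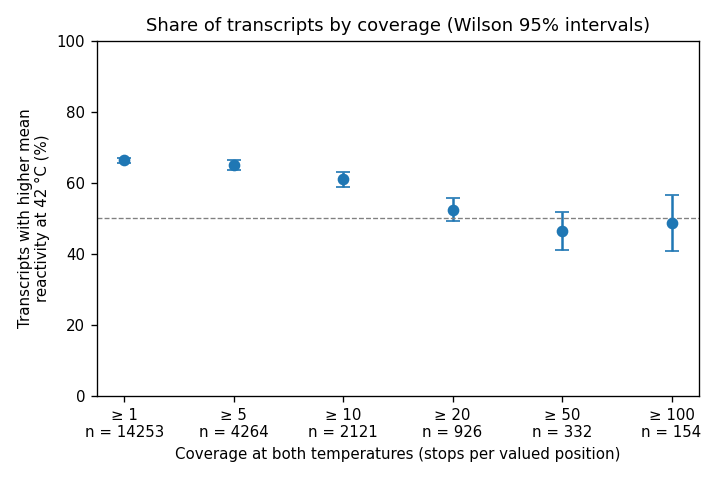
Percent of transcripts with higher mean DMS reactivity at 42 °C (y axis) in sets of transcripts with increasing minimum coverage in stops per valued position at both temperatures (x axis), with Wilson 95% intervals and the number of transcripts. The share was 66.3% over all transcripts and 46.4% at coverage of at least 50.

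HSP70 and HSP90 transcripts had lower reactivity at 42 °C. Of 23 members of that list, 19 had lower and 4 higher means at 42 °C, and the median change of -0.0681 was below every random list. Without the co-factors, 17 of 20 were lower, with a median of -0.0967, also below every random list. The HSP70 transcript OS03T0276500-01 had 0.303 at 22 °C and 0.0422 at 42 °C, a heat shock 70 kDa protein 4 (OS01T0180800-03) 0.310 and 0.0657, and HSP81-3 (OS09T0482400-01) 0.314 and 0.0952. Another transcript with that product name (OS09T0482600-01) had 0.314 and 0.0974, and whether their stops are independent was not tested. The DnaJ homolog (OS03T0787300-01) had 0.304 and 0.0762, and an FK506-binding protein (OS08T0525600-01), of a family of protein-folding isomerases, 0.320 and 0.0999. Coverage of these 6 transcripts was 2.55-fold to 14.9-fold higher at 42 °C. Their share of positions with any reactivity did not fall. It rose in all 6, from 49.4% to 58.5% in OS03T0276500-01 and from 61.5% to 62.8% in OS09T0482400-01. Their lower means thus came from lower nonzero values. Both parts also differ with depth. At 22 °C the share of reactive positions had a median of 27.6% in transcripts of low coverage (at least 1, but below 2 at either temperature). It was 64.8% at coverage of at least 50 at both temperatures, and the mean of the nonzero values was 0.729 and 0.518. The rise in share may therefore come from greater depth, and a loss of reactive positions cannot be excluded.

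The chaperonins were lower in 12 of 17 members, with a median change of -0.0287, below every random list. The heat stress transcription factors were lower in 6 of 8 members, with a median of -0.0156 at percentile 0.17, and HsfA2d had 0.241 at 22 °C and 0.0603 at 42 °C. Of the 8, 2 are heat shock factor-binding proteins, and the 6 others had a median of -0.0301, below every random list (4 lower). The other heat-response co-factors, with ascorbate peroxidases among them, were lower in 13 of 18 members, with a median of -0.00564 at percentile 1.76. The Rubisco small subunit and Calvin cycle enzymes of carbon fixation were lower in 7 of 10 members, with a median of -0.0218 at percentile 0.83. Antioxidant enzymes, which remove reactive oxygen, had a median change of 0.00328 (49 of 92 higher), which lay at percentile 1.94 because most random lists were higher still; on the common scale it was -0.00839. At coverage of at least 10, the co-factors lay at percentile 5.27 and the antioxidant enzymes at 17.0, both inside the central 95%. The organelle and rRNA list, named as a marker of RNA quality, was at percentile 2.65 in reactivity beside these lists. It was at 1.08 when matched on reactivity at 22 °C and at 0.15 with coverage of at least 10. The 5 members at that coverage had a median of -0.0516, equal to that of the 5 transcripts similar to the Rubisco large subunit. These may share stops, so the percentile does not describe RNA quality in general. The small heat shock list, with the limits given for its members, was higher in 7 and lower in 7, at percentile 22.5.

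Cell division and histone transcripts had higher reactivity at 42 °C in 66 of 85 members, with a median change of 0.0296, above every random list, and histone H3 (OS06T0130900-00) had 0.335 at 22 °C and 0.469 at 42 °C. Its histones alone were higher in 38 of 44 (median 0.0390), and its F-box proteins in 17 of 24 (percentile 69.4). Auxin and gibberellin response transcripts, of growth hormone signalling, were higher in 17 of 21 (median 0.0252, percentile 98.3), and in 17 of 19 without 2 transcripts of ribosomal protein L9 that entered by an alias (percentile 98.2). The 3 with coverage of at least 10, one such L9 transcript (OS02T0103700-01) among them, had a median of -0.00640, the value of that transcript, at percentile 29.5. Jasmonate and wound response transcripts were higher in 18 of 26 (median 0.0255, percentile 97.8, and 86.5 at coverage of at least 10), and calcium and early stress transcription factors in 24 of 33 (median 0.0224, percentile 97.7). With both tables scaled to the same overall mean, these last lists lay at percentiles 96.4 and 96.7, inside the central 95%, and the medians of all 4 stayed above 0. The cell division and calcium lists also fell in coverage (median log2 changes -0.32 and -0.22). Random lists were matched on mean coverage, not on its change. Outside the chaperone lists, at coverage of at least 5, the median log2 reactivity ratio was 0.09 at log2 coverage changes of -0.5 to 0. It was 0.18 at changes of -1 to -0.5. The cell division and calcium lists had 0.17 and 0.12, so their higher reactivity cannot be told apart from their lower coverage. In all, 10 of the 21 lists lay outside the central 95% in reactivity and 6 in coverage.

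The largest increases in reactivity among well-covered transcripts were in a Tfm5-like transcript (OS02T0662100-01), with 0.272 at 22 °C and 0.541 at 42 °C (standard error of the change over 376 positions 0.0385), and in a protein-binding protein (OS02T0616100-04), with 0.299 and 0.553. A GDSL-domain lipase (OS06T0156600-01) had 0.263 and 0.480, a WRKY transcription factor (OS02T0181300-01) 0.317 and 0.496, the cell wall enzyme XTH8 (OS08T0237000-01), which cuts and rejoins xyloglucan, 0.302 and 0.480, and a germin-like protein (OS08T0460000-01) 0.297 and 0.470.

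Along the transcript, the last 20% of the length differed most between the temperatures. Its reactivity was higher at 42 °C in 70.2% of 14224 transcripts (69.5 to 71.0), with a median change of 0.0258. The first 20% was higher in 51.8% (median change 0.00180) and the middle 20% in 49.7%. The change in the last part exceeded that in the first in 63.9% of transcripts (63.1 to 64.7), and in 58.6% (53.2 to 63.8) of 331 transcripts with coverage of at least 50, where the middle part was higher at 42 °C in 39.9%. The files do not say which end is listed first. Which part is coding was not analysed here.

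**Figure D3:**
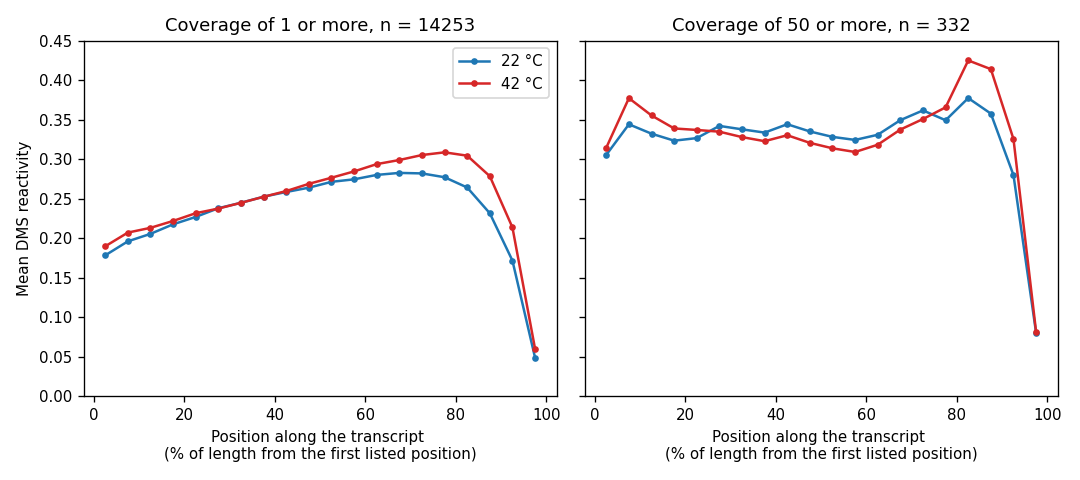
Mean DMS reactivity (y axis) in 20 bins along the transcript from the first listed position (x axis, percent of length) at 22 °C (blue) and 42 °C (red), for transcripts with coverage of at least 1 (left) and at least 50 (right). The curves part most in the last 20% of the length, where 70.2% of transcripts were higher at 42 °C.

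Transcripts whose reactivity differed most between the temperatures also differed in coverage. Both measures come from reverse transcription stops, possibly of the same libraries, and random sets matched on mean coverage do not separate them. A link between structure and abundance therefore does not follow from these values. Of 14253 transcripts, which are not independent replicates, the 713 transcripts with the largest decrease in reactivity had a median coverage change of 1.24-fold, above every random set, and held the HSP70, HSP81-3 and DnaJ transcripts described here. The 713 with the largest increase were a median 1.18-fold lower in coverage, below every random set. Among 7166 transcripts with coverage changes within 1.2-fold of the median transcript, a limit chosen after the data were seen, the set with the largest increase lay at percentile 15.3, and the set with the largest decrease, at a median log2 coverage change of 0.0448, above every random set.

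**Figure D4:**
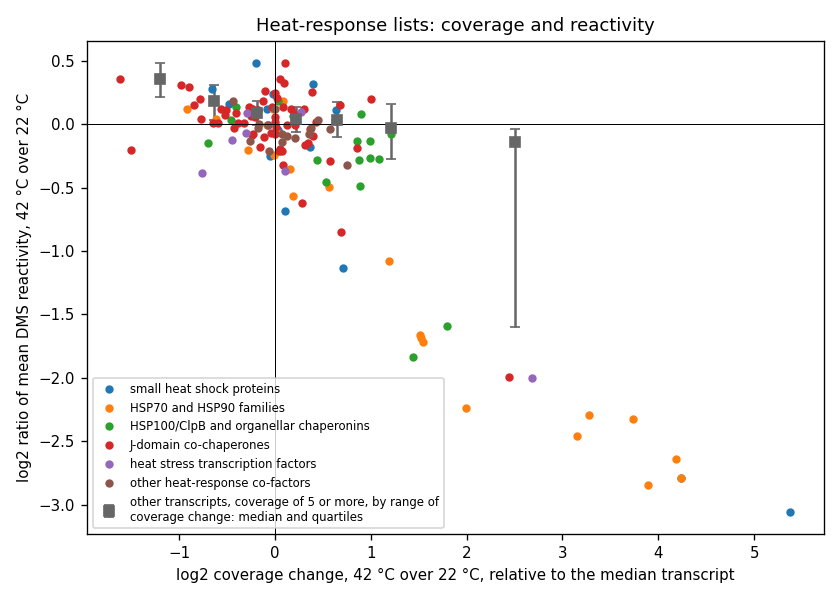
Log2 ratio of mean DMS reactivity (y axis) against log2 coverage change relative to the median transcript (x axis), 42 °C over 22 °C, for members of the 6 heat-response lists (coloured points), with the median and quartiles of other transcripts of coverage of at least 5 in ranges of coverage change (grey squares). HSP70 OS03T0276500-01 lies at a coverage change of 3.90 and a reactivity ratio of -2.84.

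In the authors' deposited table, predicted single-strandedness was higher at 42 °C in 12102 of 14290 transcripts, 84.7%, with a median difference of 1.48 percentage points. In the authors' deposited table, the HSP70 and HSP90 families had a median difference of 0.337 points, chaperonins 0.855 and heat stress transcription factors 0.781. In the authors' deposited table, the small heat shock list had 1.64, J-domain co-chaperones 1.51 and the other heat-response co-factors 1.52, while the remaining lists ran from 0.585 for epidermis to 2.00 for organelle and rRNA. By the authors' deposited table, HSP70 OS03T0276500-01 was at -1.33 points and the Tfm5-like transcript OS02T0662100-01 at 5.55. In the authors' deposited table, the folding free energy per nucleotide was higher at 42 °C in all 14290 transcripts, with a median difference of 0.149. The header of the authors' deposited table gives its unit as kJ/mol, but the grid of the values speaks against that unit, which stays open. Across 14239 transcripts, which are not independent replicates, the change in mean reactivity was compared with both differences of the authors' deposited table. Spearman's rho was 0.26 with the single-strandedness difference and 0.48 with the free energy difference of the authors' deposited table. The sources used here do not say whether these reactivities, or the temperature itself, entered the folding. The correlations and the rise in free energy in every transcript therefore cannot be read as independent evidence of changed structure.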

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

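Alternatives at coverage of at least 50 and within 1.2-fold of the median transcript, leaving out the chaperone lists, the matching of lists on 22 °C coverage, the common scale and the left-out members for lists, 1 transcript per gene, and all alternatives for coverage counts were chosen after seeing the data. No paired analysis was possible because the files hold 1 pooled profile or value per temperature and no values per library. The replicated tests, normalizations, count filters, replicate block, leave-one-out fits, library splits and fold changes of the DMS libraries planned for coverage were not run for the same reason, nor was the nucleotide split, for which no sequences were used here. The share of transcripts higher at 42 °C was 65.1% and 61.1% at coverage of at least 5 and 10. It fell below an even split at coverage of at least 50 (46.4%) and with caps at 1 (44.8%) and at the 95th percentile (49.9%). It also did so for the median (19.4%, n = 2212) and for positions above 0.5 (49.2%). On the common scale it was 49.0%, but setting the overall means equal by itself draws the share toward an even split. The share with a larger change in the last 20% of the length was 60.3% and 59.3% at coverage of at least 5 and 10, 58.6% at 50, 65.4% with at least 300 positions and 50 per part, 57.0% for the median, 61.1% for positions above 0.5 and 66.3% without the ends. The median log2 coverage change of the set with the largest increase was -0.14 at 10% set size, -0.13 at coverage of at least 10, -0.15 for log2 ratios, -0.19 for the last part and -0.0153 within 1.2-fold of the median transcript, where the limit itself bounds the change. For the set with the largest decrease it was 0.20, 0.52 and 0.14 at 10% set size, coverage of at least 10 and the last part, 0.27 without the chaperone lists and 0.0448 within 1.2-fold. At coverage of at least 10, 6 lists were set apart in reactivity in place of 10. Heat stress transcription factors had no member left, auxin and gibberellin response (percentile 29.5), co-factors, antioxidant enzymes and jasmonate response moved inside, and organelle and rRNA moved out. Otherwise the cause was not tested. Of the other values under alternatives, 9 planned and 10 added ones for main results stayed within the limits set for them, and 30 planned and 51 added percentiles of single lists kept their side of the central 95%, although some medians changed sign. Of the percentiles of single lists, 3 planned and 3 added ones moved past the central 95%, and, apart from auxin and gibberellin response, 3 planned and 2 added ones moved back inside it. Low depth limits most reactivities, with a median coverage of 2.94 at 42 °C.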

Other observations

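Of the tests in this part, only the one leaving out the members of the gene lists was chosen before its result was seen, and the matching of chaperone transcripts replaced an earlier one by nearest neighbours, few of which had risen alike. Ribosomal, translation and light harvesting transcripts lay inside the central 95% of random lists in coverage. The 152 ribosomal proteins had a median log2 change of 0.01 at percentile 43.8 and 0 members past 2-fold, and translation factors a median of -0.05 at percentile 26.2. Light harvesting and photosystem proteins, which capture light, had a median of 0.01 at percentile 19.5. Their members past 2-fold were a photosystem II 11 kDa relative (OS03T0747700-01, 2.02-fold higher) and a chlorophyll-binding family protein (OS09T0296800-01, 0.451 times its 22 °C coverage). The Rubisco small subunit and Calvin cycle enzymes had a median of 0.31 at percentile 92.9, and at 97.9 when matched on coverage at 22 °C. Proteasome and ubiquitin had a median of 0.04 at percentile 72.6, with OsUBC5b (OS02T0261100-01), an enzyme that passes ubiquitin to target proteins, 2.65-fold higher. Antioxidant enzymes had a median of 0.11 at percentile 96.9, and at 99.0 when so matched, with a glutathione S-transferase (OS01T0764000-01) 2.01-fold higher and a thioredoxin-fold protein (OS06T0320000-01) at 0.399 times its 22 °C coverage. Members singled out in this paragraph and the next were named after their values were seen.

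Hormone transcripts went both ways. Jasmonate and wound response had a median of 0.03 at percentile 62.3, with a Tify protein (OS10T0391400-01), of the family of jasmonate repressors, 2.43-fold higher and a Bowman-Birk inhibitor (OS03T0823400-01) and a lipoxygenase (OS10T0361000-01) at 0.395 and 0.427 times. Auxin and gibberellin response had a median of -0.11 at percentile 11.9, with SAUR transcripts at 2.20-fold higher (OS02T0643800-01) and at 0.338 (OS10T0510500-01) and 0.490 times (OS02T0769100-01). The mRNA decay list had a median of 0.13 at percentile 87.4, with a CCR4-associated factor (OS02T0796300-02), a subunit of the deadenylase, 2.04-fold higher. In reactivity, ribosomal proteins were higher at 42 °C in 118 of 151 members (percentile 92.0, and 98.6 when matched on reactivity at 22 °C), light harvesting in 23 of 44 (16.8), translation factors in 24 of 35 (40.4), proteasome and ubiquitin in 37 of 62 (17.4), mRNA decay in 7 of 10 (26.1) and J-domain co-chaperones in 40 of 64 (39.6). It was higher for 15 of 20 vascular (76.0), 3 of 5 epidermis (64.4), 4 of 7 aquaporin (37.6) and 7 of 14 organelle and rRNA members (2.65). Polyubiquitin (OS02T0161900-01) had 0.364 at 22 °C and 0.220 at 42 °C. In the middle of 1863 transcripts with coverage of at least 10 and at least 300 positions, reactivities 3 nucleotides apart correlated at 0.102 at 22 °C and 0.108 at 42 °C, against 0.0880 and 0.0977 at 2 and 0.0667 and 0.0700 at 4 nucleotides. Over distances of 2 to 12 nucleotides, multiples of 3 exceeded the others by a mean of 0.0228 (standard error over transcripts 0.00187) at 22 °C and 0.0197 (0.00178) at 42 °C.

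The 13 members of the chaperone lists with coverage at least 2-fold higher and of at least 5 at 22 °C had a median log2 reactivity ratio of -2.24. For 7 of them, at least 5 other transcripts had like coverage and a like rise. All 7 lay below the median of those, by a median of -1.46 (highest -0.26), which argues against the rise in depth as the whole cause. However, 3 of the 7 are HSP81-3 and HSP82 transcripts with like values that may share stops. Their 9 comparable transcripts may include those similar to the Rubisco large subunit, which had like coverage and rise and may share stops too. Of the other 6 of the 13 members, 2 had no comparable transcript and 4 had 2 each, with a median difference of -0.25. For these 6, depth and the heat response cannot be told apart because too few other transcripts rose as steeply. A candidate explanation is that RNA made during the 10 min was exposed to DMS for less time, but rho of reactivity ratio against coverage change over 65 list members, -0.75, restates the pattern and decides nothing, and at rises of 1 to 2 log2 units the 79 transcripts outside the lists had a median ratio of -0.03, against -1.68 for 6 members, and above 2 units 13 others had -0.14 with a lower quartile of -1.60. Shorter exposure and changed structure, which was not tested, cannot be told apart, since both may give this relation in the members.

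The share of transcripts with higher reactivity at 42 °C was 66.3%, and the stops were fewer at 42 °C. Among transcripts with coverage at 42 °C at or above that at 22 °C the share was 58.3%, against 69.1% in the others, which argues against lower depth as the whole cause and leaves it open as a part. With all members of the fixed lists left out, the share at coverage of at least 50 was 46.1% (39.9 to 52.4, n = 241), so the make-up of the abundant transcripts by these lists did not account for their lower share. The scale of the deposited values was not tested and stays open. The common scale moves all transcripts by 1 factor, so it cannot show an effect of scaling that differed between transcripts. At 42 °C the mean of the highest 2 to 10% of values ran from 0.918 to 1.46 over transcripts (5th to 95th percentile). A change in structure with heat, which the design names, was not tested separately.

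The larger change in the last 20% of the length than in the first held in 63.9% of transcripts and in 58.6% (53.2 to 63.8) of those with coverage of at least 50. The median excess was 0.0268 over all, 0.0205 at coverage of at least 10 and 0.0290 at 50. This argues against coverage of the whole transcript as the whole cause and leaves it open as a part. The bound for this reading, a share of 50%, was set after the values were seen. Depth at that end of the transcript itself was not tested. No biological explanation was tested.

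In the authors' deposited table, 14 transcripts had single-strandedness differences of -62.2 to -68.5 points. By the authors' deposited table these were 5068 to 7155 nucleotides long and filled the first 14 lines, 28 other transcripts of over 5000 nucleotides had a median of 1.15, and the lowest value elsewhere was -10.3.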
